A study of Mus musculus with 6 samples.

How the data were processed

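ATAC-seq libraries of lineage-negative bone marrow cells from 6 mice were compared, 3 wildtype and 3 Mel18 knockout, grouped by the genotype in the labels. Per the labels' protocols, cells were lysed and incubated with Tn5, and the tagmented DNA was purified, amplified and barcoded. The submitters' processing notes name the build mm10 and, with no role or order, FastQC, MultiQC 0.11.5, Trimmomatic 0.40, Bowtie2 1.2.2, Picard and MACS2 2.1.1. The tool that counted reads, any shift of reads for the Tn5 offset, any removal of duplicates and any filter on peaks are not given in the sources used here, and these steps can move the counts. Some of these version numbers do not look like those of the tools beside them and are printed as listed.

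Per the file headers, the deposited table gives for each of 109859 peaks its position, the nearest transcription start site, raw read counts in 6 libraries, and a comparison of knockout with wildtype. The counts are whole numbers with a different total in each library and were deposited without normalization. The authors' log2 fold change and mean log2 CPM, and the authors' p-value and adjusted p-value per peak, were used only where the text names the deposited table. An edgeR likelihood ratio test with robust dispersions gave p-values within 1.2e-07 of the deposited ones. The table numbers libraries within a genotype and the labels number the mice across both, so a library is known by its group only. No count column was assigned to a mouse, and 12 other columns of values per library were not used. Peak starts are counted from 0 in the table and from 1 in the text. The labels give separate mice, so the libraries of a group are biological replicates. Pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 2.258 to 9.492), so none was counted as a duplicate. Total counts ran from 12000808 to 16709921, with a median of 40 to 63 reads per peak. Intervals on shares would cover counting error only, and the text uses the spread between libraries in their place.

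The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; robust, TMM normalization, filterByExpr, which removed no peak), with Benjamini-Hochberg adjustment over all peaks and a threshold of 0.05. Every adjusted p without another name comes from it, and those of gene lists from camera. CPM values use TMM library sizes. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Log2 CPM values used a prior count of 2. A promoter peak lay within 1 kb of a start site. Levels were split into 10 deciles by mean log2 CPM. Single values per library were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Trended normalization used a loess curve of each library against mean level (span 0.3) as offsets. A scaling by library size alone moved the median log2 fold change of all peaks from 0.02 to 0.14.

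Gene lists (16 lists, 397 genes, 360 with a peak) were fixed before the data were examined, as were the tests, the main alternatives and the rule for named peaks. They covered PRC1, PRC2, Hox genes, developmental transcription factors, stem cell, myeloid, erythroid, megakaryocyte, B cell, T and NK cell, mast cell with basophil and eosinophil, macrophage and dendritic, and stromal and endothelial genes, cell cycle and p53 genes, AP-1 and immediate early genes, and the interferon response. Peaks were assigned to genes by the table's nearest start site. Lists were tested with camera (limma 3.58.1, preset correlation, and an estimated correlation as alternative) and fry, adjusted over the 16 lists. The named peaks were those annotated to Pcgf2, the strongest passing peaks overall and per list, and, since fewer than 5 passed in each direction, the 5 with the smallest p each way, at most 1 per gene, given as not passing. Other named peaks were chosen after their values were seen, and the text says so; those from the authors' table and those passing over a list alone are named because they are few, apart from a result that is not reported here. Of 19013 gene symbols in the table, 18160 were found in a gene table of the matching assembly, which gave the positions of Pcgf2 and Mx1.

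The pipeline was tested on simulated data for this comparison, with 200 changed peaks among 107828. It called 2 of 67 at 1.5-fold (2.99%), 8 of 67 at 2-fold (11.9%) and 50 of 66 at 4-fold (75.8%), with 8 false calls. A shift of 0.5 log2 units planted in the stem cell list was recovered with preset and estimated correlation, and the preset also called 1 list more. Simulated peaks were drawn independently of each other. In the data the estimated correlation was 0.0636 for T and NK genes and 0.213 for myeloid genes. The recovery therefore does not show how the estimated correlation performs on such lists. Alternatives were DESeq2 1.42.0 (its Wald test, and its size factors in edgeR), limma-voom, library sizes alone, trended normalization, no filter, a mean of at least 50 reads, an adjusted p under 0.01, at least 1.5-fold, autosomes only, a 3 kb promoter window and each library left out. Motif shares and a GC correction need a genome sequence and were not run. Chosen after seeing the data were the likelihood ratio test and the trended fit without wildtype library 3.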

Results

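Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in lineage-negative bone marrow cells. These are the cells left after mature blood cells are removed, a fraction rich in hematopoietic stem and progenitor cells. Mel18 is a Polycomb group protein encoded by Pcgf2, a subunit of the repressive complex PRC1. Libraries came from 3 wildtype mice and 3 mice in which Mel18 was removed conditionally in the blood system, and the question was whether its loss changes accessibility. The table analysed held read counts in 109859 peaks with a median width of 197 bp. Wildtype libraries 1, 2 and 3 held 12000808, 12166259 and 13769335 peak reads. Knockout libraries 1, 2 and 3 held 16709921, 14487908 and 14797735. Each knockout library held more peak reads than each wildtype library, the most extreme arrangement of 3 against 3 (exact two-sided permutation test, p = 0.1, the smallest p this design allows). Only reads within peaks were counted, so sequencing depth itself was not compared. Library numbers are those of the table, which does not say which mouse each came from.

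Wildtype library 3 stood apart. Its mean Spearman correlation with the other wildtype libraries, across peaks, was 0.859. The mean within the own group was 0.896 for wildtype library 1, 0.894 for wildtype library 2 and 0.939 to 0.949 for the knockout libraries. Wildtype libraries 1 and 2 are lowered here by their pairs with wildtype library 3, and correlated at 0.931 with each other. With the knockout libraries the means were 0.922, 0.94 and 0.876 for wildtype libraries 1, 2 and 3. The leading principal component, with 41.2% of the variance, placed wildtype library 3 at 182.4 and the other 5 libraries between -63.49 and 2.31. The second, with 22.9%, placed wildtype libraries between 8.588 and 118.6 and knockout libraries between -81.56 and -32.34. Total peak reads separate the groups in the same way. Chromosome X peaks took 1.94% ± 0.0601 of reads in wildtype and 1.92% ± 0.0226 in knockout (SD, n = 3 each; exact two-sided permutation test, p = 0.7). The table had 0 peaks on chromosome Y, so the sex of the mice was not checked.

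The locus of the deleted gene showed no detectable difference. By the deposited annotation, no peak had the Pcgf2 transcription start site as its nearest, which does not show that its promoter lacks a peak. The peak closest to Pcgf2 lies on chromosome 11 from 97702450 to 97702803 (mm10), 16 bp beyond the higher coordinate of the annotated gene, which spans 97688821 to 97702434. The strand of the gene was not used, so whether the peak lies on its promoter side is not stated. The table assigns this peak to Psmb3, a proteasome subunit gene. It held 16.7 ± 3.04 CPM in wildtype and 17.7 ± 1.83 CPM in knockout (SD, n = 3 each), a log2 fold change of 0.09 ± 0.188 (SE; adjusted p = 0.935). The 2 neighbouring peaks, at 97703084 to 97703492 over the start of Psmb3 and at 97703595 to 97703667 in its intron, had log2 fold changes of -0.13 ± 0.103 and -0.14 ± 0.399 (SE; adjusted p = 0.779 and 0.957). Within 100 kb of Pcgf2 on either side, the median log2 fold change of 35 peaks was -0.08 and the smallest adjusted p was 0.327. The deleted exons are not given in the labels, and a peak outside them does not test the deletion.

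At individual peaks, the Mx1 promoter gave the clearest signal of higher CPM in knockout cells, though it missed the threshold in the main test. Extra copies of this segment in the knockout genome would also raise the reads, so higher accessibility is not shown. Mx1 encodes an interferon-induced antiviral GTPase. Its promoter peak, on chromosome 16 from 97462853 to 97463285 and overlapping the annotated exon and intron at the gene's start, held 12.7 ± 0.791 CPM in wildtype and 30.3 ± 2.3 CPM in knockout (SD, n = 3 each). This was 2.38-fold, a log2 fold change of 1.25 ± 0.151 (SE), and the groups did not overlap (edgeR quasi-likelihood test, adjusted p = 0.0506). A second peak further upstream, from 97463312 to 97463432, held 0.441 ± 0.182 CPM in wildtype and 2.95 ± 0.916 CPM in knockout, a 6.58-fold difference (log2 fold change 2.72 ± 0.441, SE; adjusted p = 0.0606). Among the 129 peaks of the interferon list, these 2 passed when p was adjusted over the list alone, at 0.000297 and 0.00288.

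**Figure D1:**
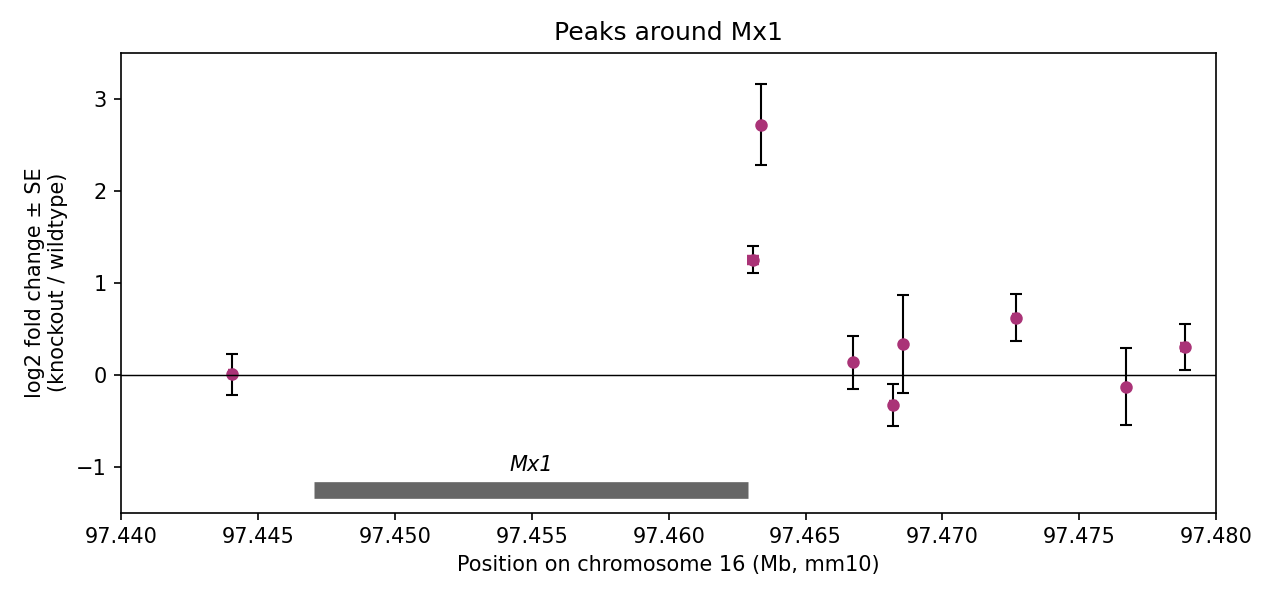
Log2 fold change of normalized reads, knockout over wildtype, for the peaks around Mx1, plotted against position on chromosome 16 (mm10). Points are peaks, error bars are standard errors of the edgeR fit and the grey bar is the annotated gene. The promoter peak at 1.25 and the peak upstream of it at 2.72 stand above the other 7 peaks, which lie between -0.33 and 0.62.

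Across all peaks, 0 were higher and 0 were lower in knockout at an adjusted p under 0.05 (edgeR quasi-likelihood test, smallest adjusted p = 0.0506), and DESeq2 also called 0, though it gave an adjusted p for only 5493 peaks and none for the Mx1 promoter. At an unadjusted p under 0.05 there were 9967 peaks, 3409 higher and 6558 lower, against 5493 expected by chance. DESeq2 gave 6784 at that level. Without wildtype library 3, 319 peaks were higher and 2694 lower past the threshold, a count that trended normalization brought to 44 and 73, and at promoters from 37 and 1764 to 26 and 7. Without wildtype library 2, 1 was higher and 533 lower. With size factors from DESeq2 in edgeR the counts were 2 and 466, and with limma-voom 1 and 278. The authors' deposited table holds 2 higher peaks and 1 lower peak past an adjusted p of 0.05. The higher ones are the Mx1 pair, with deposited adjusted p-values of 4.3e-05 and 0.000262. The lower one lies on chromosome 6 from 10690607 to 10690885, 283632 bp from the nearest annotated start (AA545190). It held 3.93 ± 1.59 CPM in wildtype and 0.393 ± 0.229 CPM in knockout (SD, n = 3 each), with a log2 fold change of -3.28 ± 0.496 (SE; edgeR quasi-likelihood test, adjusted p = 0.0606).

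The peaks with the smallest p in each direction, at most 1 per gene, differed in kind. The 5 lower ones were strong promoter peaks with small differences. At Suco, a gene for a SUN-domain protein of the endoplasmic reticulum, the peak on chromosome 1 from 161876575 to 161877083 held 266.3 ± 12.5 CPM in wildtype and 189.3 ± 2.06 CPM in knockout (SD, n = 3 each; log2 fold change -0.49 ± 0.0539, SE; adjusted p = 0.0506). The promoter peaks of Tmem55b, Strn (the scaffold protein striatin), Pgrmc2 and Slc25a3 (the mitochondrial phosphate carrier) had log2 fold changes of -0.53, -0.54, -0.54 and -0.48, with adjusted p-values of 0.0506 for all but Slc25a3, at 0.0578. With trended normalization, which removes differences that follow the level of a peak, these 5 values shrank to between -0.20 and -0.10. After Mx1, the higher peaks lay away from promoters. A peak 16503 bp upstream of Sgpp1, a sphingosine phosphate phosphatase gene, on chromosome 12 from 75752158 to 75752305, held 0.355 ± 0.0824 CPM in wildtype and 1.69 ± 0.317 CPM in knockout (SD, n = 3 each; log2 fold change 2.22 ± 0.441, SE; adjusted p = 0.0757). Intronic peaks at Iqgap2 and Mir467f and a peak 22925 bp upstream of Fbxw11, within an intron of Stk10, had log2 fold changes of 1.47, 1.38 and 0.98, with adjusted p-values from 0.0951 to 0.0967.

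Promoter peaks took a smaller share of reads in knockout libraries. Of the 109859 peaks, 21892 (19.9%) lay within 1 kb of a transcription start site, and they held 53.9% ± 1.7 of reads in wildtype and 50.2% ± 0.284 in knockout (SD, n = 3 each). The ranges, 52.54 to 55.8% and 49.85 to 50.41%, did not overlap (exact two-sided permutation test, p = 0.1, the smallest possible). The strongest 10% of peaks held 56.8% ± 0.538 in wildtype and 52.7% ± 0.182 in knockout, again without overlap (p = 0.1, exact). With 0 peaks past the threshold, the planned test of called peaks between promoters and other sites had nothing to compare. At an unadjusted p under 0.05, 244 promoter peaks were higher and 4182 lower, against 3165 and 2376 elsewhere. The odds of lying on the lower side were 22.8 times greater at promoters (Fisher's exact test, two-sided, 95% interval 19.8 to 26.3; peaks are not independent replicates), and 13.4 times greater with a 3 kb promoter window (95% interval 11.9 to 15). With trended normalization the counts were 412 and 847 at promoters and 2201 and 2734 elsewhere, and the odds fell to 1.65 times (95% interval 1.45 to 1.89). The median log2 fold change was -0.15 at promoters, 0.07 in introns and 0.07 between genes, and with trended normalization -0.07, 0.01 and 0.02.

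**Figure D2:**
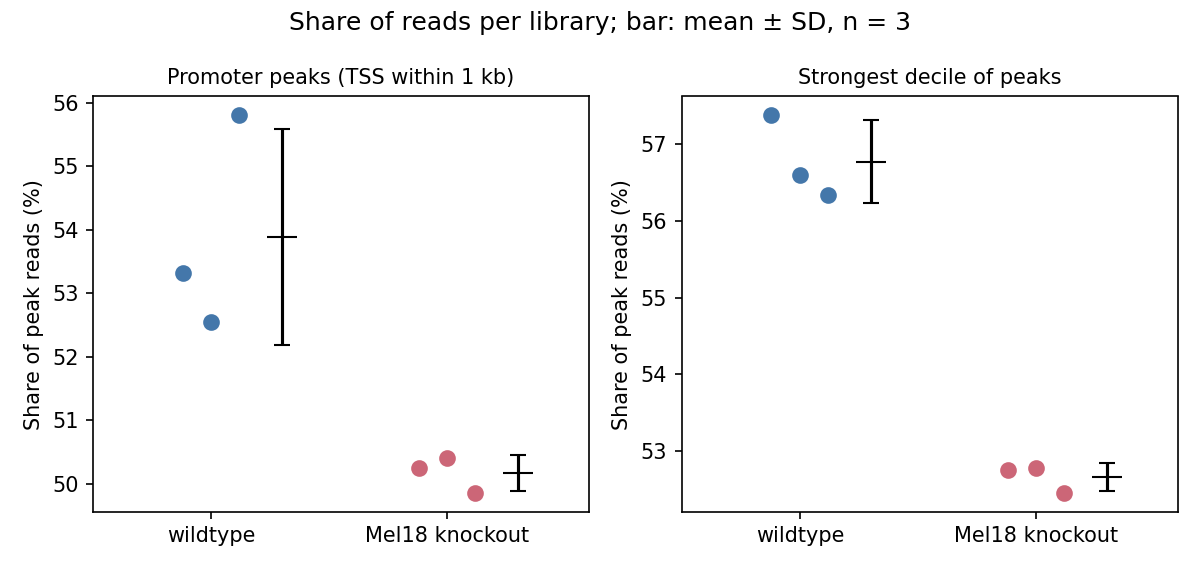
Share of peak reads, in percent, in promoter peaks and in the strongest decile of peaks, with 1 point per library and the mean ± SD of 3 libraries per group beside the points. Knockout libraries lie at 49.85 to 50.41% for promoters, below the 52.54 to 55.8% of wildtype libraries. The vertical axes do not start at 0.

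The difference followed the level of the peaks. In the weakest decile the median log2 fold change was 0.17, in the strongest -0.21, and in the strongest decile 32 peaks were higher and 4262 lower at an unadjusted p under 0.05. Promoter peaks of that decile had a median of -0.245 and other peaks of -0.12. Trended normalization brought the decile medians to between -0.02 and 0.02, left 6194 peaks at an unadjusted p under 0.05 and called 0.

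**Figure D3:**
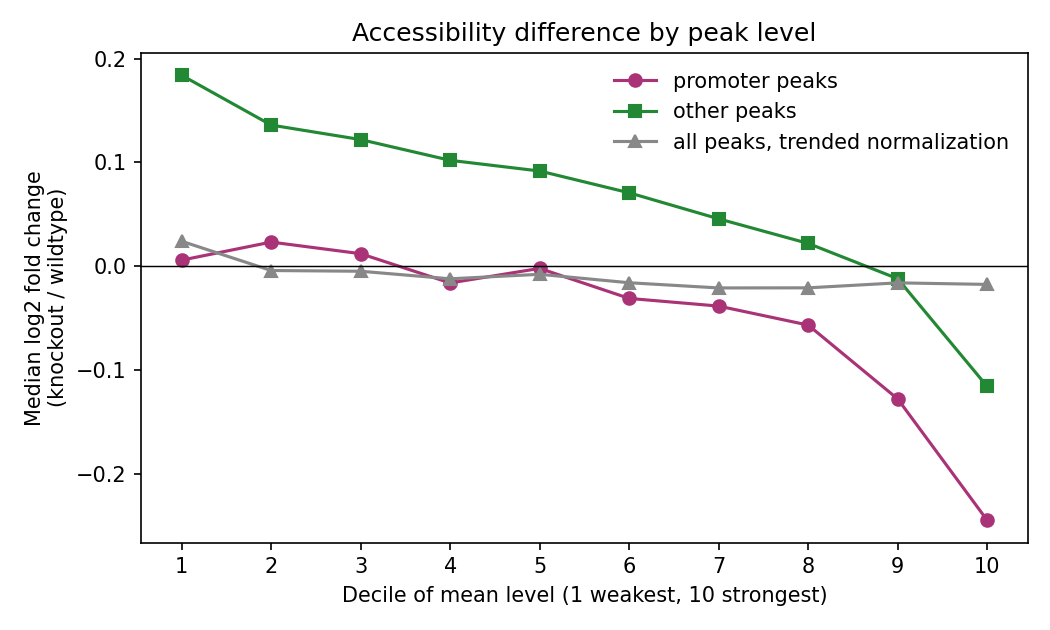
Median log2 fold change, knockout over wildtype, by decile of mean level, for promoter peaks, for other peaks and for all peaks after trended normalization. Other peaks run from 0.18 in the weakest decile to -0.12 in the strongest, and promoter peaks end at -0.245, while the trended values stay near 0.

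Among the gene lists, peaks assigned to T and NK cell genes had lower values in knockout on balance, with overlapping libraries. None of their 230 peaks passed on its own, over all peaks or adjusted over the list alone, yet 36 were lower and 0 higher at an unadjusted p under 0.05, and the median log2 fold change was -0.17. These counts were 24 and 8 with library sizes alone, 63 and 6 without wildtype library 2, and 17 and 1 without knockout library 3, with medians of -0.05, -0.26 and -0.17. The list was called by camera with its preset correlation (adjusted p = 3.37e-05), and not with an estimated correlation (adjusted p = 0.552) or by fry (adjusted p = 0.331). Its mean level per library did not separate the groups, as wildtype library 2 lay at -0.07 and knockout library 2 at -0.01 around the mean of the 6 libraries (exact two-sided permutation test, p = 0.2). Of its 24 genes, 19 had a mean log2 fold change under 0. The smallest p belonged to the promoter of Il2rb, a chain of the interleukin receptor on T and NK cells, with 11.04 ± 3.46 CPM in wildtype and 4.84 ± 0.605 CPM in knockout (SD, n = 3 each; log2 fold change -1.19 ± 0.265, SE; adjusted p = 0.111). Next came peaks near Gzmb, a cytotoxic granule protease, and within Tcf7, a T cell transcription factor, at -1.43 ± 0.327 and -1.47 ± 0.344 (SE; adjusted p = 0.119 and 0.127). These 3 were chosen after their values were seen. Wildtype library 3 had the highest level for this list, 0.22 log2 units above the mean of the 6 libraries. Without it the median was -0.13 and the list was not called (adjusted p = 0.1), while with trended normalization as well, a setting chosen after seeing the data, the median was -0.17 and the list was called (adjusted p = 0.00155; 0.678 with an estimated correlation).

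Myeloid genes, which include the granule proteins of neutrophil precursors, were called higher by camera (201 peaks, median log2 fold change 0.14, adjusted p = 0.0438). The call was lost with an estimated correlation (adjusted p = 0.763), library sizes alone (0.0536), trended normalization (0.0605), and without knockout library 2 (0.0937) or knockout library 3 (0.0567). With the preset correlation it held without wildtype library 1 (adjusted p = 0.00501; 0.655 with an estimated correlation) and wildtype library 2 (7.06e-05; 0.701). It also held without knockout library 1 (0.038; 0.778) and with promoter peaks only (0.00551; 0.885). Of these peaks 10 were higher and 6 lower at an unadjusted p under 0.05. At Mpo, the myeloperoxidase gene, the promoter peak held 5.37 ± 0.579 CPM in wildtype and 9.88 ± 1.96 CPM in knockout (SD, n = 3 each; adjusted p = 0.19), and peaks near Irf8, a transcription factor of monocyte development, went the other way, with the smallest p at a log2 fold change of -1.13 ± 0.322 (SE; adjusted p = 0.233). Both genes were chosen after their values were seen. In wildtype library 3 the list lay 0.47 log2 units below the mean of the libraries, and without that library the direction turned and the list was not called (adjusted p = 0.69).

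The other lineage lists were not called in the main test, and the calls below, all with the preset correlation, were lost with an estimated correlation. Stem cell genes had a median of 0.10 over 455 peaks (adjusted p = 0.0655), with 26 peaks higher and 13 lower at an unadjusted p under 0.05. Among the higher were peaks near Runx1 (1.10) and Hlf (0.95). Fli1 had peaks on both sides, with -1.01 at 71629 bp upstream of its start and 0.80 at 91 bp from it. All of these were chosen after their values were seen. Stromal and endothelial genes had a median of 0.13 (adjusted p = 0.0656) and macrophage and dendritic genes 0.13 (0.127). Mast cell, basophil and eosinophil genes had 0.13 (0.157) and B cell genes -0.12 (0.157). With trended normalization these medians were 0.06, 0.08, 0.05 and -0.135, and that of stem cell genes 0.06. The values above therefore carry part of the trend with level, except for B cell genes. Stem cell genes were called higher without knockout library 2 (adjusted p = 0.0432; 0.649 with an estimated correlation) and stromal and endothelial genes without wildtype library 2 (0.0397; 0.225). Macrophage and dendritic genes were called higher without wildtype library 1 (adjusted p = 0.019; 0.655 with an estimated correlation), wildtype library 2 (0.0397; 0.739) and knockout library 1 (0.038; 0.778). B cell genes were called lower with trended normalization (adjusted p = 0.0255; 0.636 with an estimated correlation), without knockout library 2 (0.0432; 0.772) and with promoter peaks only (6.68e-05; 0.617), where the comparison is with all peaks and promoters as a class had lower values. Megakaryocyte genes had a median of -0.01 (adjusted p = 0.812) and erythroid genes -0.03 (0.951), the latter tested as higher. Without wildtype library 3, in which erythroid peaks lay 0.29 log2 units above the mean, erythroid genes were called higher (adjusted p = 0.00237; 0.634 with an estimated correlation), and also when trended normalization was added (0.00155; 0.784). With library sizes alone or trended normalization their direction was lower, without a call.

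**Figure D4:**
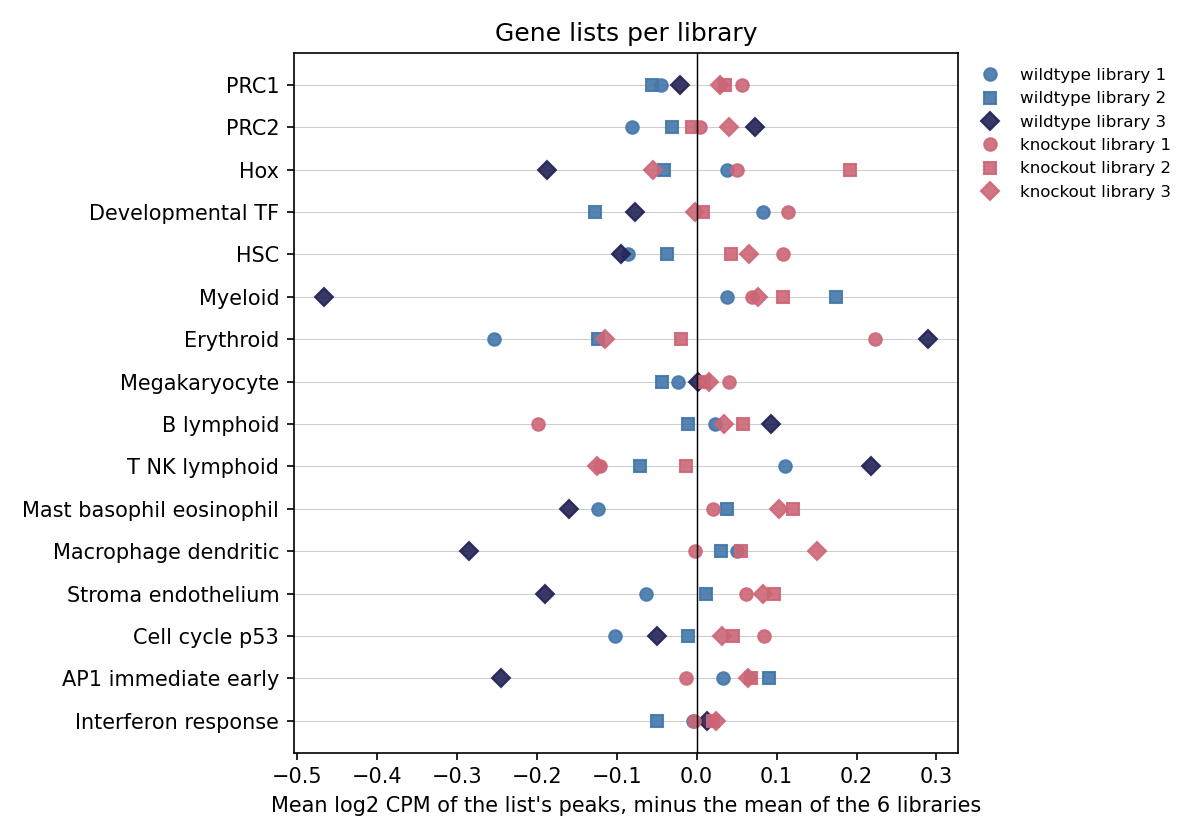
Mean log2 CPM of the peaks of each gene list in each of the 6 libraries, minus the mean over the libraries. Each symbol is a library. Wildtype library 3, the dark diamonds, lies at -0.47 for myeloid genes and at 0.29 for erythroid genes, outside the other libraries for both.

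Polycomb genes and their classic targets were not called either. PRC1 subunit genes had a median of 0.01 over 221 peaks (adjusted p = 0.812) and PRC2 subunit genes 0.01 over 103 peaks (0.647). Hox genes, the textbook Polycomb targets, had a median of 0.14 over 37 peaks (0.545), and other developmental transcription factor genes 0.05 over 181 peaks (0.769). With trended normalization the medians of the Hox and developmental lists were 0.06 and -0.05. The direction of the PRC1 and developmental lists turned to lower with trended normalization, without a call. With promoter peaks only, PRC1 and PRC2 genes were called lower (adjusted p = 0.00551 and 4.18e-05; 0.834 and 0.165 with an estimated correlation), against all peaks, among which promoters had lower values. The PRC2 list tested lower while its median and mean lay just above 0. Adjusted over the list alone, 1 PRC1 peak was lower, in an intron of Pcgf5, on chromosome 19 from 36409457 to 36410003, with 87.4 ± 6.26 CPM in wildtype and 63.0 ± 1.63 CPM in knockout (SD, n = 3 each; log2 fold change -0.47 ± 0.0823, SE; adjusted over the list alone 0.0191, over all peaks 0.0606). With trended normalization its log2 fold change was -0.21.

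Of the remaining lists, cell cycle and p53 genes had a median of 0.06 (adjusted p = 0.365), AP-1 and immediate early genes 0.03 (0.734) and interferon response genes -0.01 (0.812). The interferon and megakaryocyte lists tested lower, with means just above 0. Adjusted over the list alone, 1 cell cycle peak was lower, near the cyclin gene Ccne1 (log2 fold change -0.40 ± 0.0696, SE; adjusted over the list alone 0.0244), which shrank to -0.08 with trended normalization. Outside the PRC1, cell cycle and interferon lists, no list held a peak that passed in this way.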

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

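The likelihood ratio test and the combination of trended normalization with leaving out wildtype library 3 were chosen after seeing the data. The count of 0 peaks past the threshold stood with library sizes alone, trended normalization, no filter (which removes no peak and so tests nothing), a mean of at least 50 reads, the DESeq2 test, autosomes only, a stricter threshold and a fold minimum. It rose to 468 with DESeq2 size factors (436 at promoters), 279 with limma-voom (264), 3 with the likelihood ratio test (2), and 117 with trended normalization without wildtype library 3 (44 higher and 73 lower; 33 at promoters, 26 higher and 7 lower). Leaving out libraries gave 0 to 3013 peaks (0 to 1801 at promoters), with 3013 without wildtype library 3, 534 without wildtype library 2 (450 at promoters) and 0 for each other library. All 468 and all 279 were among the 3013. In the strongest decile of level, where values were lower in knockout, lay 466 of the 468 and all 279. So did 487 of the 534 and 2327 of the 3013. The cause was not tested. DESeq2 gave an adjusted p for 5493 peaks.

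The promoter minus other difference in median log2 fold change, -0.21, became -0.0739 with trended normalization and 0.000439 when wildtype library 3 was also left out. The top minus bottom decile difference, -0.38, became -0.0416 and -0.0463, as the trend with level was what these settings remove. In the other settings both moved by less than 1 SD between libraries, though the former fell to -0.129 without wildtype library 3. The share of reads in promoter peaks differed by -4.39 to -2.76 percentage points (knockout minus wildtype) with each library left out.

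Of 2 gene lists called, 0 remained with an estimated correlation, and with it no list was called in any setting (smallest adjusted p = 0.165). The number called was 2 with trended normalization (T and NK genes and B cell genes, not myeloid genes), 1 with library sizes alone, 5 with promoter peaks only, and 1 to 4 with libraries left out (1 without wildtype library 3 or knockout library 3, 4 without wildtype library 2). Directions turned, given as adjusted p, for PRC1 (0.938, trended; 0.00551, promoter peaks), developmental genes (0.637, trended; 0.279, promoter peaks), erythroid genes (0.813, library sizes; 0.809, trended; 0.0632, promoter peaks), and, with promoter peaks, cell cycle genes (0.0811) and megakaryocyte, macrophage and AP-1 genes (0.754 each). With trended normalization without wildtype library 3 they turned for PRC2, Hox and interferon genes (0.804 each), developmental and AP-1 genes (0.687 each), macrophage genes (0.694) and myeloid genes (0.3). Leaving out libraries turned at least 1 direction in lists with adjusted p of 0.321 to 0.925 (PRC2), 0.193 to 0.934 (developmental), 7.06e-05 to 0.69 (myeloid), 0.00237 to 0.877 (erythroid), 0.697 to 0.932 (megakaryocyte), 0.019 to 0.925 (macrophage), 0.1 to 0.932 (AP-1) and 0.653 to 0.933 (interferon). The causes were not tested, except that promoter peaks as a class had a lower median.

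The peak closest to Pcgf2 ranged from -0.0459 without wildtype library 3 to 0.183 with libraries left out, and the other 2 peaks there reached 0.107 with trended normalization, 0.0765 and 0.335 with that library also left out, and -0.48 to 0.46 with libraries left out. Of the other named peaks none turned, apart from the peak nearest the start of Fli1, which was not followed through the settings. The Mx1 promoter peak (1.2 to 1.38) passed in 6 of the 15 settings that gave it an adjusted p. The DESeq2 test gave it none. Simulated 1.5-fold changes were called in 2.99% of cases, so this depth and replication leave small differences undetected. Motif shares and a GC correction were not run. No paired analysis was possible because the mice carry no shared numbers across genotypes.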

Other observations

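The tests below were chosen after the results they bear on were seen, except the count of T and NK genes under 0. A mean log2 fold change under 0 was found for 14 of the 18 B cell genes with a peak and 16 of 23 interferon genes, for 13 of 23 erythroid, 13 of 24 AP-1 and 11 of 21 PRC1 genes, and for 6 of 30 stem cell and 6 of 25 myeloid genes; these shares were not tested against each other. Among T and NK genes the means were lowest at Il2rb (-0.88), Lck (-0.59), Gzmb (-0.57), Bcl11b (-0.50) and Cd3g (-0.49), and above 0 at Thy1 (0.11), Cd8a (0.11), Ncr1 (0.07), Tbx21 (0.05) and Cd4 (0.04). The lower peak on chromosome 6 in the authors' deposited table, far from any annotated start, held 47, 63 and 30 reads in wildtype libraries and 9, 8 and 2 in knockout libraries.

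Higher CPM at the Mx1 promoter was seen in each of the 3 knockout libraries. An interferon response that opened the promoters of its genes together is argued against: 35 promoter peaks of the other interferon list genes had a median log2 fold change of -0.106 (bootstrap 95% interval over peaks -0.213 to -0.0145). All promoter peaks had a median of -0.146, so this value is not a fall particular to interferon genes. The difference with level is also argued against, since the Mx1 promoter peak stood at 1.35 under trended normalization. A candidate explanation is extra copies of the promoter segment in the knockout genome, as a transgene driven by the Mx1 promoter would bring; conditional deletion in blood is often done with such a transgene, but the labels name no driver. The other 7 peaks of the locus had a median of 0.136 (interval -0.131 to 0.337), which leaves this explanation open, as it does an opening of the endogenous promoter alone.

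Strong peaks had lower values in knockout. If knockout libraries held less signal over background, strong peaks away from promoters would be lower as well, and their top minus bottom decile difference was -0.301 (interval -0.315 to -0.286), consistent with that explanation. Weak peaks called more often from the knockout libraries, which held more peak reads, would leave the upper levels flat. The top minus 6th decile difference of -0.269 (interval -0.277 to -0.262) argues against this as the only source. Which libraries each peak was called in was not examined. The promoter difference left after the trend is removed may come from wildtype library 3, since it was 0.000439 without that library (interval -0.00404 to 0.00516). These intervals resample peaks and leave out the spread between libraries. Before the trend was removed, the SD between libraries was 0.09 for promoter minus other peaks and 0.0529 for top minus bottom decile. The source of the small promoter difference is therefore not settled. A loss of accessibility at strong sites through the genotype stays open and untested, because total peak reads, level trend and genotype separate the libraries in the same way.

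Without wildtype library 3 the median of the T and NK loci stayed below 0, at -0.134 (interval over genes -0.179 to -0.0698), but the list was not called. The interval leaves out the spread between libraries, so it cannot decide whether that library carried the difference. Around the mean of the 6 libraries, wildtype library 1 lay at 0.111 log2 units. Wildtype library 2 lay at -0.0707, below knockout library 2 at -0.0134. The trend with level is argued against, since the median was -0.232 with it removed (interval -0.399 to -0.147). More residual T and NK cells in the wildtype sorts may explain the pattern, as 19 of 24 list genes had a mean under 0, and 21 of 24 without wildtype library 3. Lineage depletion would remove such cells, the strongest wildtype peaks ran from 1.41 CPM at Cd8a to 41.9 at Cd3d and 85.6 at Klrb1c, and all 24 genes have peaks in these libraries. The count of genes under 0 leaves out size. Without wildtype library 3 the mean went from -0.591 to -0.151 at Lck and from -0.494 to -0.0919 at Cd3g. At Cd3d it went from -0.131 to -0.276. Any cause that lowers the list as a whole would also give a high count. Fewer lymphoid-primed progenitors in knockout marrow would look alike and was not tested.

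The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 0 peaks and the highest other split 1, and as any split reaches 0 this count tests nothing. The real split called 2 gene lists and the other splits from 2 to 6, so this count does not set the real split apart. A structure among the libraries besides genotype may be the reason, which was not tested. The T and NK list was called in 4 of the other splits, with adjusted p from 1.4e-07 to 0.0187, the smallest below the 3.37e-05 of the real split. At an unadjusted p under 0.05 the real split gave 9967 peaks and the highest other 10297.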
